A study of Mus musculus with 40 samples.

How the data were processed

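T cells were profiled from the livers of male C57BL/6 mice that were 6 to 8 weeks old when the diets began. Livers were perfused and digested and the cells enriched for live CD3+ cells before 5′ single-cell RNA and T cell receptor libraries were made, so that the labels list 40 samples, an RNA library and a receptor library for each of 20 preparations. Each preparation was treated as 1 mouse, and chow library 16and19 at 25 weeks, whose name joins 2 numbers, may hold cells of 2 mice. Reads were processed with Cell Ranger 6.0.1 against mm10 per the submitters. The cell filter, any removal of free RNA, the treatment of doublets, the clustering method and the normalisation call are not given in the sources used here. No doublets were called or removed here. No raw reads were used.

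The deposited expression matrix held 32285 genes and 64808 cells as natural log values, ln(1 + UMIs per 10000 UMIs of the cell). This unit was checked on the values: after exp(value) − 1 every cell summed to 10000, and 100% of values were whole multiples of 1 UMI within a tolerance of 0.02. Of the listed entries 2.739% were 0. A deposited table gave each cell its library, diet, weeks, cluster (24 clusters), cell type name, and its receptor sequences and clone label as the authors assigned them. Since the authors named the cell types from the same expression values, tests between cell types or of genes that define them are not independent of the annotation.

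The clusters under each name were checked by their leading genes. The Tex clusters (7, 9, 10 and 11), Naive/Tcm clusters of CD8 T cells (2 and 4) and the Treg cluster (8) carried the markers of their names, and cluster 11 took 93.84% of its cells from HFHC library 3 at 31 weeks. The CD4 class did not, through clusters 0, 13 and 15, nor did the Effector/Tem subset and the CD8 class, through clusters 12 and 20, which were led by pancreatic and hepatocyte genes. Cluster 1 was shallow, with a median of 1439 UMIs and a receptor in 22.07% of its cells.

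For each library, linear values were averaged over the cells of a class and multiplied by 100 to give CPM, the UMIs per 1000000 UMIs of a cell, and log2(mean CPM + 5) was analysed with limma 3.58.1 in R 4.3.3 (statmod 1.5.0), with a mean-variance trend and robust empirical Bayes. Genes with a mean of at least 10 CPM over libraries were tested, in 1 model with all 5 groups for CD8 T cells and another for CD4 T cells. A class of a library needed at least 20 cells. Adjusted p values are Benjamini-Hochberg over all genes tested in a comparison, with a threshold of 0.05. The comparisons were HFHC with chow at 25 weeks, HFHC with chow at 31 weeks, reversal with HFHC, reversal with chow, and the difference between the HFHC effects at 31 and 25 weeks. Expanded cells were compared with cells of single-cell clones by limma on the difference within each mouse.

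Named genes were the 10 higher and the 10 lower genes with the largest log2 change among those past the threshold with at least 25 CPM in the higher group, leaving out receptor and immunoglobulin segments, ribosomal, mitochondrial, haemoglobin, histone, unnamed and sex-linked genes, and always Cd8a, Cd8b1, Cd4, Pdcd1, Tox, Cxcr6, Gzmk and Gzmb. From each gene list the 3 genes with the smallest p and the gene with the highest level could be named. The comparisons, this rule, 35 gene lists and most alternatives were fixed before the data were examined. Lists of at least 3 genes past the filter (20 of the 35) were tested with camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation, and with fry. The other 15 lists had fewer, and their genes are given singly. The lists covered T cell states (cytotoxic effector, exhaustion-associated, tissue residency, circulating effector, naive or central memory, T cell receptor signalling response), cell processes (dissociation stress, proliferation, interferon response, cholesterol synthesis and uptake, cholesterol efflux, fatty acid use, glycolysis, oxidative phosphorylation, AP-1 and NF-kB regulators, chemokine and cytokine receptors) and markers of CD8, CD4, regulatory, Th1 or follicular helper, Th17, Th2 or type 2 innate lymphoid, gamma-delta, and natural killer T or MAIT cells, of B, plasma, natural killer, dendritic, macrophage or Kupffer, red or platelet cells, neutrophils, hepatocytes, cholangiocytes, endothelial cells and stellate cells.

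Clones were defined by the authors' label within a library. Expanded means 2 or more CD8 T cells of a clone in a library, and expanded shares and clone probabilities were computed from CD8 T cells with a receptor, the shares after thinning each library to 346 cells (100 draws). Shares, clonality, V gene use (each clone counted once) and shared CDR3 sequences were compared with 2-sided exact permutation tests in Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3. With 4 mice per group there are 70 arrangements, and the smallest p is 0.0286. Figures were drawn with matplotlib 3.10.9. Depth limits the expression values most in the reversal group, where the median CD8 T cell had 1705 to 3788 UMIs, and the share of CD8 T cells with a receptor was 42.1 to 66.1% there, 82.2 to 92.6% and 60.2 to 78.3% on chow and HFHC at 25 weeks, and 81.4 to 91.0% and 70.5 to 81.3% at 31 weeks.

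The expression test was tested on simulated data with an assumed dispersion. It recovered 14.93%, 84.62% and 100% of genes changed 1.5-, 2- and 4-fold in the 25-week comparison. Within groups, libraries correlated at 0.915 to 0.992 and differed by more than counting noise, so none was a duplicate. Mice at 31 weeks carry the numbers 1 to 4 in each group, and these numbers were checked for pairing. No paired analysis was possible at 25 weeks because the numbers of the chow and HFHC libraries do not overlap. Alternatives included other pseudocounts and filters, the mean of the deposited log values, recovered UMIs summed per mouse, the median gene set equal across mice, only the compared groups in the model, the replicate number as a block, CD8 cells chosen by transcripts (Cd8a or Cd8b1 above 0 and Cd4 at 0), a fixed mix of CD8 subsets, other sizes and definitions of clones, and leaving out each library. Alternatives chosen after seeing the data left out clusters 1, 12 and 20, cluster 1, cluster 12 or cluster 13, kept only cells with a receptor, only cluster 0 or only the CD4 Naive/Tcm cluster, or kept only the 31-week mice. The sex-linked genes left out of the named genes were Xist, Tsix, Ddx3y, Uty, Kdm5d and Eif2s3y, and other genes of the X chromosome, such as Bex3, were not left out. Some genes are withheld for evaluation and are not reported here: they stay in the counts of genes and lists, and were left out of the single-gene rows of the sensitivity analysis and of the outlier tests after their values were seen.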

Results

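T cells isolated from the livers of mice on a high-fat high-cholesterol diet (HFHC), a diet that induces fatty liver inflammation, or on chow were profiled by 5′ single-cell RNA sequencing together with sequencing of their T cell receptors. The 20 RNA libraries fell into 5 groups of 4: chow at 25 weeks, HFHC at 25 weeks, chow at 31 weeks, HFHC at 31 weeks, and a reversal group that received HFHC for 26 weeks and then chow for 5 weeks. The matrix held 64808 cells, between 758 and 7766 per library, with 2951540 to 33300642 UMIs (unique molecular identifiers) per library and a median of 2446 to 5757.5 UMIs per cell. The authors' annotation, made on the same expression values, named 41125 cells CD8 T cells (427 to 6117 per library), of which 30679 had a receptor sequence (346 to 3890 per library), and 15244 cells CD4 T cells (92 to 3838 per library). A Cd4 UMI was found in 1.37 to 22.4% of the CD8 T cells of a library, so a low level of Cd4 in this class was not read as expression.

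The libraries differed with diet in measures of depth and RNA content. The median depth of CD8 T cells was 6050 to 6994 UMIs on chow and 3701 to 4375 on HFHC at 25 weeks. At 31 weeks it was 3773 to 5542 on chow, 3188 to 4337 on HFHC and 1705 to 3788 in the reversal group. Transcripts of ribosomal proteins made up 29.8 to 33.4% of the RNA of CD8 T cells on chow and 17.5 to 20.03% on HFHC at 25 weeks, and 27.6 to 33.3%, 18.3 to 28.3% and 12.2 to 18.9% at 31 weeks in the same order. A cluster of shallow cells, cluster 1, held 3.49 to 12.9% of CD8 T cells on chow and 21.2 to 32.3% on HFHC at 25 weeks. At 31 weeks it held 1.83 to 7.75% on chow, 0.053 to 23.8% on HFHC and 25.4 to 51.5% in the reversal group. In HFHC library 4 at 31 weeks, 96.5% of the CD8 T cells lay in cluster 12, which was led by genes of pancreatic digestive enzymes and took 1818 of its 1829 cells from this library. Nearly all of cluster 20, led by the hepatocyte gene Fabp1, came from HFHC library 21 at 25 weeks (493 of 494 cells). Because clusters 1, 12 and 20 fell within the annotated CD8 class, the counts of CD8 genes in the 4 comparisons of diets are given with and without them.

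The first comparison asked how CD8 T cells of the liver differed between HFHC and chow at 25 weeks. CD8 T cells from HFHC livers expressed inhibitory receptors far above those from chow livers: Pdcd1, which encodes PD-1, averaged 331 ± 87.8 CPM (SD, n = 4) against 13.8 ± 2.81 CPM, and Tigit averaged 354 ± 72.5 against 20.3 ± 5.24 CPM. The transcription factor gene Tox, which maintains exhausted CD8 T cells, rose from 94.0 ± 6.62 to 427 ± 54.3 CPM, and Gzmk, which encodes the granule protease granzyme K, from 89.1 ± 26.8 to 726 ± 68.8 CPM. Ccr7, a gene of naive and recirculating T cells that encodes the receptor guiding them into lymph nodes, was lower, at 77.9 ± 32.5 CPM on HFHC and 458 ± 81.8 CPM on chow. The cell types shifted in the same mice, with exhausted CD8 T cells (Tex) at 28.2 ± 9.5% of CD8 T cells on HFHC and 1.45 ± 0.61% on chow, and naive or central memory cells (Naive/Tcm) at 13.6 ± 7.2% and 78.7 ± 5.0% (2-sided exact permutation tests, n = 4 per group, p = 0.0286 each, the smallest p this design allows, Benjamini-Hochberg (BH) adjusted over 3 subsets 0.0286).

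Of 16 exhaustion-associated genes measured at 25 weeks, 14 rose and none fell over all genes tested, and 15 rose adjusted over the list alone. Their set test had an adjusted p of 4.05e-06 (camera) and an adjusted p = 0.549 with an estimated correlation. Of 14 naive or central memory genes, 10 fell and none rose by either adjustment, with an adjusted p of 9.05e-16 (camera) and an adjusted p = 0.140 with an estimated correlation. Of 15 cytotoxic effector genes, 11 rose and 1 fell by either adjustment, with an adjusted p of 0.0272 (camera) and an adjusted p = 0.732 with an estimated correlation. They included the chemokine genes Ccl3 (log2 fold change 3.74, SE 0.63) and Ccl4 (3.43, SE 0.45) and the protease gene Gzmb (2.45, SE 0.56). All 4 measured markers of regulatory T cells, of 6 listed, rose by either adjustment (camera, adjusted p 0.0132, and adjusted p = 0.237 with an estimated correlation). This list shares genes with the exhaustion-associated list, Ctla4 among them, so it is not a separate sign of regulatory T cells. The list of oxidative phosphorylation genes was lower than other genes (camera, adjusted p 0.0238, and adjusted p = 0.732 with an estimated correlation), although its median log2 change was only −0.04, with 1 of 18 genes higher over all genes and none adjusted over the list alone. The remaining named genes with large changes at 25 weeks were Coch (4.58, SE 0.77), Penk, which encodes an opioid peptide precursor (3.71, SE 0.86, with an SD of 132 CPM around a mean of 133 on HFHC), the inhibitory receptor genes Havcr2 (3.53, SE 0.66), Lag3 (3.43, SE 0.62) and Lilrb4a (2.99, SE 0.38) and, among those lower, Igfbp4 (−2.86), Dapl1 (−2.63), Tdrp (−2.63), Actn1 (−2.21), Rgcc (−2.18), the gut-homing receptor gene Ccr9 (−2.18), Treml2 (−2.08) and Tmem108 (−2.07). The tissue-homing receptor gene Cxcr6 rose by 1.40 (SE 0.36) and Cd8b1 fell by 0.45. Cd8a had a log2 change of 0.36 (adjusted p 0.247, limma) and Cd4 of 1.07 (adjusted p 0.168, limma).

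Of 8133 genes tested in CD8 T cells, 3951 passed an adjusted p of 0.05 at 25 weeks, 3418 higher and 533 lower on HFHC (limma). The median change of all genes was 0.26 log2, and with the median gene set equal across mice 2397 genes passed, 1070 higher and 1327 lower, with 13 exhaustion-associated genes higher and 11 naive or central memory genes lower. Without clusters 1, 12 and 20, 2410 genes passed, 1680 higher and 730 lower, with 14 exhaustion-associated genes higher and 11 naive or central memory genes lower. In that setting 8 of 18 oxidative phosphorylation genes rose and none fell. When each mouse was given the same mix of 62.5% Effector/Tem and 37.5% Naive/Tcm cells, which leaves out Tex, 2 genes passed, and Pdcd1 had a log2 change of 2.30 (adjusted p 0.237, limma). In that setting Cxcr6 (−0.15) and Gzmb (−0.19) turned direction. The Effector/Tem part of this mix included clusters 1, 12 and 20, and a library had as few as 25 Naive/Tcm cells for its other part.

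**Figure D1:**
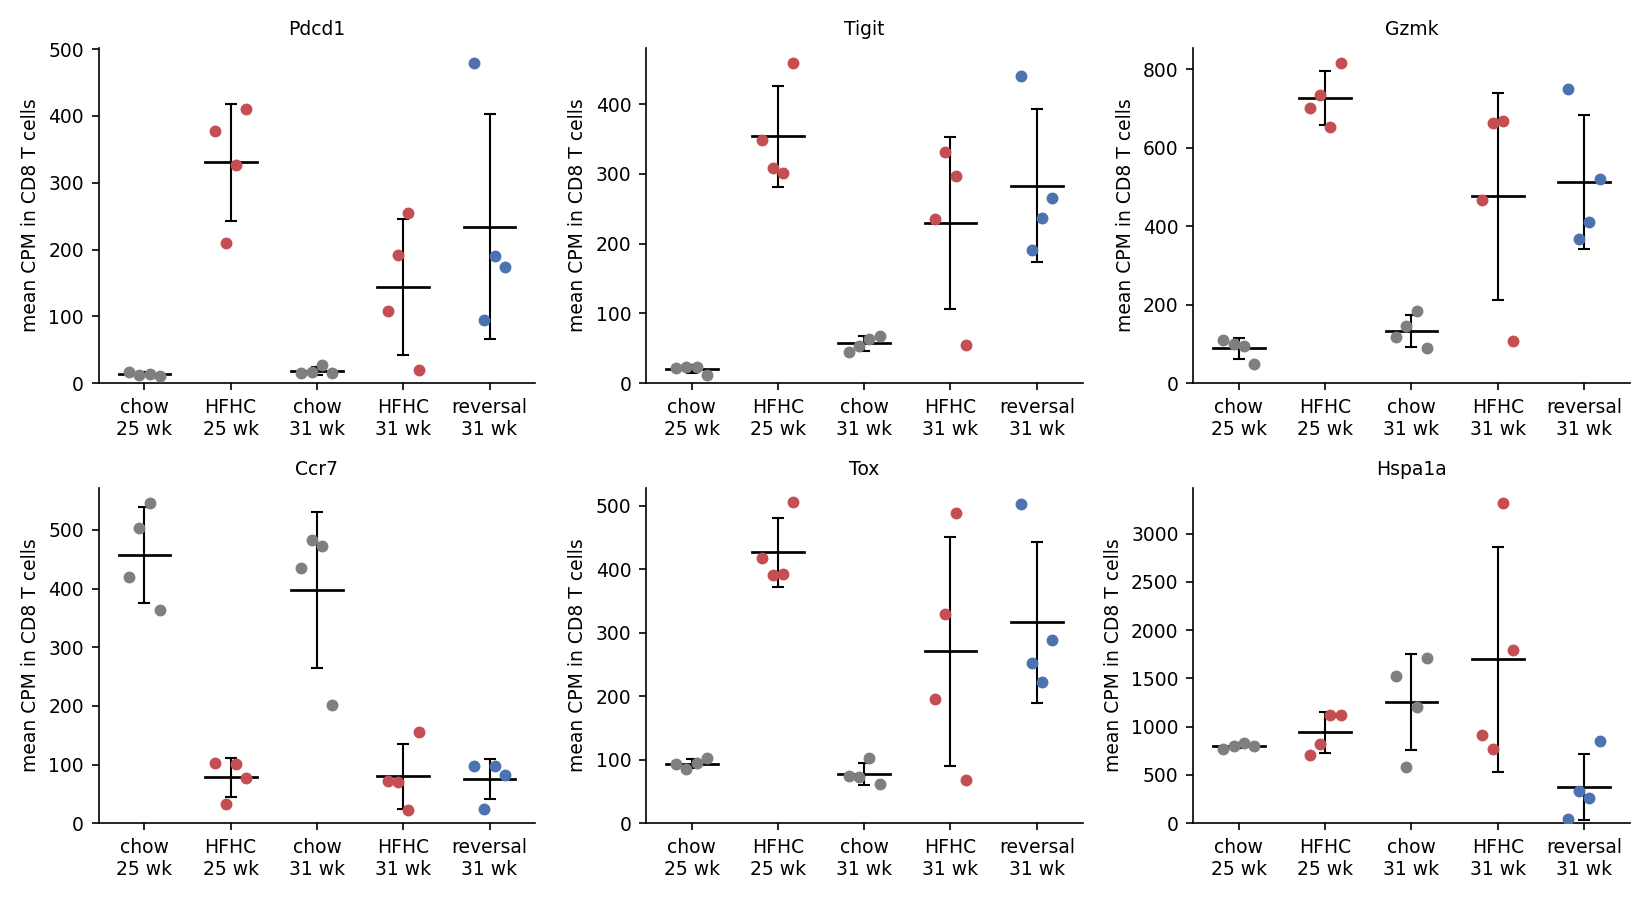
Mean expression in CD8 T cells (CPM, vertical axis) of 6 named genes in the 5 groups (horizontal axis), with 1 point per mouse, a black line at the mean and an error bar of 1 SD. Pdcd1 averaged 331 CPM in HFHC mice at 25 weeks against 13.8 CPM on chow, while Ccr7 averaged 77.9 against 458 CPM.

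At 31 weeks the same question was asked of mice kept on HFHC or chow for the whole time. Pdcd1 averaged 144 ± 102 CPM (SD, n = 4) on HFHC and 18.6 ± 6.05 CPM on chow, a log2 change of 2.25 (SE 0.58, adjusted p 0.0237, limma). The inhibitory receptor genes Havcr2 (2.20, SE 0.66) and Lag3 (2.12, SE 0.62), Tox (1.44, SE 0.41), Cxcr6 (1.22, SE 0.36) and Gzmk (1.54, SE 0.45) rose as well. Without clusters 1, 12 and 20 Cxcr6 (1.05, adjusted p 0.133, limma) and Gzmk (1.59, adjusted p 0.0738) did not pass. Cxcr6 did not pass with the median gene set equal across mice either (1.08, adjusted p 0.0621). Ccr7 fell to 80.3 ± 55.5 from 398 ± 133 CPM. Naive/Tcm cells made up 8.73 ± 7.13% of CD8 T cells on HFHC and 57.0 ± 18.4% on chow (2-sided exact permutation test, n = 4 per group, p = 0.0286, BH over 3 subsets 0.0858). Tex cells made up 32.6 ± 24.8% and 3.16 ± 1.82% (exact p = 0.143), and 43.4% on HFHC without library 4 (exact p = 0.0286).

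Of the 16 exhaustion-associated genes, 11 rose and none fell at 31 weeks (13 rose adjusted over the list alone, camera adjusted p 1.71e-06, and adjusted p = 0.492 with an estimated correlation). Of the 14 naive or central memory genes, 11 fell and none rose (12 fell adjusted over the list alone, camera adjusted p 1.83e-19, and adjusted p = 0.0677 with an estimated correlation). Regulatory T cell markers, which share genes with the exhaustion-associated list, rose in 2 of 4 genes and in 4 adjusted over the list alone (camera adjusted p 0.0410, and adjusted p = 0.492 with an estimated correlation). The set test placed dissociation stress genes (adjusted p 0.0381, and adjusted p = 0.636 with an estimated correlation) and oxidative phosphorylation genes (adjusted p 0.0225, and adjusted p = 0.678 with an estimated correlation) below other genes by camera. In the first of these 1 gene rose and 1 fell by either adjustment and both the median (0.05) and the mean (0.01) log2 change were above 0, the opposite sign to the test, and in the second none passed by either adjustment. Among the other named genes, Adgrg1 (2.33), the signalling regulator gene Rgs16 (2.06), Setbp1 (2.01), the growth factor gene Csf1 (1.75), Ttn (1.70), Nrp1 (1.70) and Cables1 (1.69) rose, and Dapl1 (−2.27), Igfbp4 (−2.14), Tdrp (−1.92), Fam241a (−1.63), Fcgrt (−1.58), Nsg2 (−1.56), Actn1 (−1.54) and Sh3bp5 (−1.51) fell. Of these Rgs16, Setbp1, Csf1, Ttn, Cables1 and Fcgrt did not pass without clusters 1, 12 and 20. Gzmb had a log2 change of 1.05 (adjusted p 0.194), Cd8a of 0.42 (adjusted p 0.251), Cd8b1 of −0.22 (adjusted p 0.387) and Cd4 of 0.89 (adjusted p 0.333) by limma.

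At 31 weeks 1135 of 8133 genes passed in CD8 T cells, 869 higher and 266 lower on HFHC (limma), with a median change of 0.134 log2. With the median gene set equal, 866 passed, 376 higher and 490 lower, and without clusters 1, 12 and 20, 698 passed. The count depended on single libraries: it was 3078 without HFHC library 4, 431, 198 and 147 without HFHC libraries 1, 2 and 3, and 320, 140 and 230 without chow libraries 1, 2 and 3. With only the compared groups in the model 3 genes passed. Pdcd1 (adjusted p 0.114), Havcr2, Lag3, Tox, Cxcr6, Gzmk and Ccr7 were not among them. With a fixed mix of subsets none did (limma, 754 at an unadjusted p under 0.05). In that mix Cxcr6 (−0.11), Gzmk (−0.15) and Gzmb (−0.57), the last not past the threshold before, turned direction and Pdcd1 had a log2 change of 0.60 (adjusted p 0.711). Without HFHC library 4, Pdcd1 rose by 2.96 (SE 0.42, adjusted p 0.000187, limma), and 15 exhaustion-associated genes rose.

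The diet effects at 25 and 31 weeks, each measured against its own chow group, were compared gene by gene. The inhibitory receptor genes Pdcd1, Havcr2 and Lag3 rose at both times and the naive T cell gene Ccr7 fell at both. Across 8133 genes the log2 changes had a Spearman rho of 0.766, where genes are not independent replicates. Of the genes called at either time, 806 rose at both (365.2 by chance) and 217 fell at both (17.43 by chance), and 0 were called in opposite directions. A test of the difference between the effects named 5 genes (limma, 933 at an unadjusted p under 0.05), picked out after their values were seen. The HFHC effect was larger at 31 weeks for the interferon-inducible gene Ifi208 (difference in log2 change 1.298), and smaller for Ankrd37 (−1.47), the glucocorticoid-induced gene Fkbp5 (−1.19), the adhesion molecule gene Icam1 (−0.85) and Bex3 (−0.71). The number was 8 without HFHC library 3 of 31 weeks and 2 or 3 when any of 14 other single libraries was left out. The times were measured in different mice, so an effect of duration cannot be told apart from a batch of animals.

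**Figure D2:**
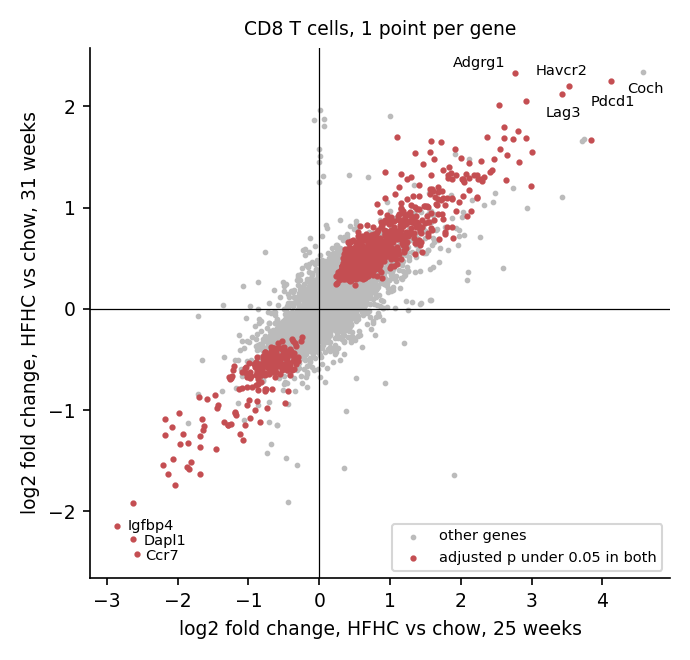
Log2 fold change of HFHC against chow in CD8 T cells at 25 weeks (horizontal axis) and at 31 weeks (vertical axis), with 1 point per gene for 8133 genes and red for genes with an adjusted p under 0.05 at both times. Of the red genes 806 were higher and 217 lower at both times, and 0 differed in direction.

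The reversal group was compared with mice kept on HFHC to ask what 5 weeks of chow changed. The chaperone gene Hspa1a was lower after the return to chow, with 373 ± 342 CPM (SD, n = 4) against 1696 ± 1168 CPM on HFHC, and Hspa1b and Dnajb1 fell by 2.26 and by 1.37 on the log2 scale, but none of the 3 passed without HFHC library 4. The RNA-binding protein gene Zfp36l2, which promotes mRNA decay, rose from 815 ± 102 to 2038 ± 438 CPM, and Malt1, a signalling protease downstream of the T cell receptor, from 166 ± 51.4 to 433 ± 186 CPM. Reversal library 2 had Malt1 at 710.1 CPM, and the log2 change of 1.34 was 1.08 without it. Without cluster 1 Zfp36l2 stayed past the threshold (1.19, adjusted p 0.0251, limma) and Malt1 did not (0.47, adjusted p 0.125). Pdcd1 averaged 234 ± 168 CPM after reversal and 144 ± 102 CPM on HFHC (log2 change 0.87, adjusted p 0.293, limma) and did not pass, and the changes of Tox (0.46, adjusted p 0.443), Gzmk (0.34, adjusted p 0.614), Gzmb (−0.01, adjusted p 0.996) and Cxcr6 (−0.24, adjusted p 0.656) did not pass either. Without HFHC library 4 the change of Pdcd1 was 0.17 (adjusted p 0.847). Tox (−0.07) and Gzmk (−0.26) turned direction and Gzmb was at −0.17, none past the threshold. Tex cells made up 33.6 ± 17.4% of CD8 T cells after reversal and 32.6 ± 24.8% on HFHC (2-sided exact permutation test, n = 4 per group, p = 0.943). On HFHC without library 4 they made up 43.4%, which turned the difference to −9.78 points (exact p = 0.429).

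None of the exhaustion-associated or naive and central memory genes passed between reversal and HFHC, by either adjustment. Of 19 dissociation stress genes 5 fell over all genes (Hspa1a, Hspa1b, Dnajb1, Hsp90ab1 and Hspa8) and 6 adjusted over the list alone (camera adjusted p 1.58e-06, and adjusted p = 0.246 with an estimated correlation). Over all cells, Hspa1a ranged from 42.95 to 944.2 CPM in reversal libraries and from 757.9 to 3161 CPM in libraries of the other 4 groups. The set test also placed oxidative phosphorylation genes (adjusted p 1.58e-06, and adjusted p = 0.605 with an estimated correlation) and interferon response genes (adjusted p 1.44e-05, and adjusted p = 0.605 with an estimated correlation) below other genes by camera. Of these 0 of 18 and 1 of 16 genes fell, and none adjusted over the list alone. Cholesterol synthesis and uptake genes, which cells raise when sterols are scarce, included 7 of 14 that rose, among them Insig1 (0.94), Idi1 (0.71) and Cyp51 (0.65). Adjusted over the list alone 8 rose and 1 fell, with an adjusted p of 0.0744 by camera, 0.605 with an estimated correlation and 0.00279 by fry, which tests against no change, while the median of all genes was 0.127 log2 and that of the list 0.335. Fry also called T cell receptor signalling (adjusted p 0.0108) and AP-1 and NF-kB regulators (0.0223) higher and dissociation stress lower (0.0322). The cholesterol list was higher in reversal than in chow too, with 8 of 14 genes higher and 1 lower (fry, adjusted p 5.72e-05). Its called genes still measured kept a median of 40.2% of their log2 change without cluster 1, and 73.98% without clusters 1, 12 and 20. Among the other named genes, Lilr4b (1.45), the stress sensor gene Ern1 (1.302), the AP-1 gene Fosl2 (1.17), the pro-apoptotic gene Bcl2l11 (1.15), Lncpint (1.03), Slc25a36 (1.03, but −0.0094 without cluster 1), Ttn (1.003) and the phosphatase gene Ptpn22 (0.98) rose. Acaa2 (−1.05), Ahcy (−0.87), Atp5k (−0.78), Ndufb1-ps (−0.72), Cyb5a (−0.66), Ubb (−0.63) and Polr2j (−0.60) fell. None of the genes from Lilr4b to Polr2j in these lists stayed past the threshold without cluster 1 or without clusters 1, 12 and 20, where Ern1 was too low to be tested. Insig1 did not pass in the latter setting (0.35, adjusted p 0.443, limma). Cd8a (−0.30), Cd8b1 (−0.42, adjusted p 0.0984) and Cd4 (0.20) did not pass.

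Between reversal and HFHC 989 of 8133 genes passed, 854 higher and 135 lower (limma), with a median change of 0.127 log2. With the median gene set equal 913 passed, 309 higher and 604 lower. Without cluster 1 alone 5 genes passed, and without clusters 1, 12 and 20 only 3, with no dissociation stress or cholesterol gene among the latter, although the log2 changes of Hspa1a (−2.41, adjusted p 0.307, limma) and Hspa1b (−2.14, adjusted p 0.340, limma) stayed near those with all cells. The count was 59 without HFHC library 4, 363 and 2247 without HFHC libraries 1 and 3, and 73 without reversal library 2, and 0 genes passed with only the compared groups in the model (limma, 1487 at an unadjusted p under 0.05). Without HFHC library 4, 1 cholesterol gene rose, no dissociation stress gene fell, and Hspa1a had a log2 change of −2.40 (adjusted p 0.104).

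Reversal was also compared with chow at 31 weeks, to ask how far the cells of mice returned to chow differed from those never given HFHC. Pdcd1 was higher by 3.13 log2 (SE 0.58, adjusted p 0.000367, limma), with 234 ± 168 against 18.6 ± 6.05 CPM (SD, n = 4), and Ctla4, another inhibitory receptor gene, by 2.52 (SE 0.43, adjusted p 0.000207). Tox (1.90), Havcr2 (3.04), Gzmk (1.89) and Cxcr6 (0.98) were higher as well, and Ccr7 (−2.40) and the naive cell regulator Id3 (−1.78) lower. Cxcr6 did not pass with the median gene set equal across mice (0.67, adjusted p 0.123, limma) or without clusters 1, 12 and 20 (1.25, adjusted p 0.0581). Of 16 exhaustion-associated genes, 13 were higher and none lower (14 adjusted over the list alone, camera adjusted p 0.00291, and adjusted p = 0.752 with an estimated correlation). Of 14 naive or central memory genes, 11 were lower and none higher (12 adjusted over the list alone, camera adjusted p 1.49e-10, and adjusted p = 0.224 with an estimated correlation). Tex cells were at 33.6 ± 17.4% of CD8 T cells against 3.16 ± 1.82% and Naive/Tcm cells at 9.27 ± 4.45% against 57.0 ± 18.4% (2-sided exact permutation tests, n = 4 per group, p = 0.0286 each, BH over 3 subsets 0.0429).

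Further genes higher after reversal than on chow were Coch (3.77), Csf1 (2.94), Cables1 (2.90), Setbp1 (2.75), Adgrg1 (2.73), Ttn (2.71) and Ier5l (2.48). Igfbp4 (−2.73), Dapl1 (−2.71), Hspa1a (−2.22), Tdrp (−2.04), Actn1 (−2.02), Hspa1b (−1.96), Tmem108 (−1.91) and Cd8b1 (−0.64) were lower. Dissociation stress genes were lower in 10 of 19 cases and higher in 2 by either adjustment (camera adjusted p 3.00e-06, and adjusted p = 0.224 with an estimated correlation), and oxidative phosphorylation genes lower in 8 of 18 by either adjustment (camera adjusted p 3.00e-06, and adjusted p = 0.752 with an estimated correlation). Gzmb (1.05, adjusted p 0.119), Cd8a (0.13, adjusted p 0.691) and Cd4 (1.09, adjusted p 0.151) did not pass by limma. In all, 4584 genes passed, 3692 higher and 892 lower (limma), with a median change of 0.259 log2. With the median gene set equal 4183 passed, 1771 higher and 2412 lower. The count was 1264 without clusters 1, 12 and 20, with 13 exhaustion-associated genes higher and 13 naive genes lower, and 2696 with a fixed mix of subsets, in which Cxcr6 (−0.22), Gzmk (−0.12) and Gzmb (−0.49) turned direction. Cluster 1 stayed within the Effector/Tem cells of that mix, so the share of shallow cells was not held fixed, and 9 named genes became weaker in it.

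The genes called at 25 weeks, outside receptor segments, were followed into the reversal comparison to ask whether they moved back. The 3415 genes higher at 25 weeks, Pdcd1 and Tox among them, had a median log2 change of 0.29 on HFHC against chow at 31 weeks and of 0.22 in reversal against HFHC, so their median lay further from chow and not nearer to it (limma's rotation test fry, p 0.0201). Of these, 585 (17.13%) were lower after reversal, with 9 called lower and 526 called higher. The 531 genes lower at 25 weeks, Ccr7 among them, had medians of −0.38 and −0.16 (fry, p 0.110), with 160 higher after reversal, 10 called higher and 44 called lower. Against chow, reversal had medians of 0.52 and −0.57 in these sets. The median of the first set in reversal against HFHC was 0.08 (fry p 0.257) without clusters 1, 12 and 20, 0.13 (fry p 0.0872) with the median gene set equal, 0.11 (fry p 0.0532) without HFHC library 4 and 0.20 (fry p 0.0557) without reversal library 1. The median of the second set was −0.24 (fry p 0.0172) with the median gene set equal and −0.25 (fry p 0.0195) without HFHC library 3.

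The share of T cells that were CD8 T cells was 81.5 ± 2.6% on HFHC and 65.7 ± 4.6% on chow at 25 weeks, and 82.4 ± 9.6% and 50.3 ± 12.99% at 31 weeks (2-sided exact permutation tests, SD, n = 4 per group, p = 0.0286 each, BH over 4 comparisons 0.0571). In the reversal group it was 69.8 ± 11.5% (exact p = 0.143 against HFHC and 0.0857 against chow). Regulatory T cells made up 8.32 ± 2.41% of all cells on HFHC and 2.33 ± 2.21% on chow at 25 weeks (exact p = 0.0286, BH over 9 cell types 0.0515). CD4 Naive/Tcm cells made up 1.42 ± 0.83% against 13.6 ± 4.03% (exact p = 0.0286, BH 0.0515). The effect on the CD8 share differed between the times by 16.3 points (exact permutation over 4900 arrangements, p = 0.0963). In HFHC library 4 at 31 weeks the annotated CD8 share was 91.99%, while 39.8% of T cells were CD8 cells by their Cd8a, Cd8b1 and Cd4 transcripts. With CD8 cells chosen by transcripts in every mouse, the differences between HFHC and chow were 5.44 points at 25 weeks (exact p = 0.343) and 15.6 points at 31 weeks (exact p = 0.143). This choice depends on depth: a Cd8 UMI was found in 53.93% of cells of shallow cluster 1 and in 86.9% of cluster 3. Since CD8 T cells on HFHC were shallower at 25 weeks, it may understate their share. Without clusters 1, 12 and 20 they were 11.2 (BH 0.114) and 14.8 points (exact p = 0.343).

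**Figure D3:**
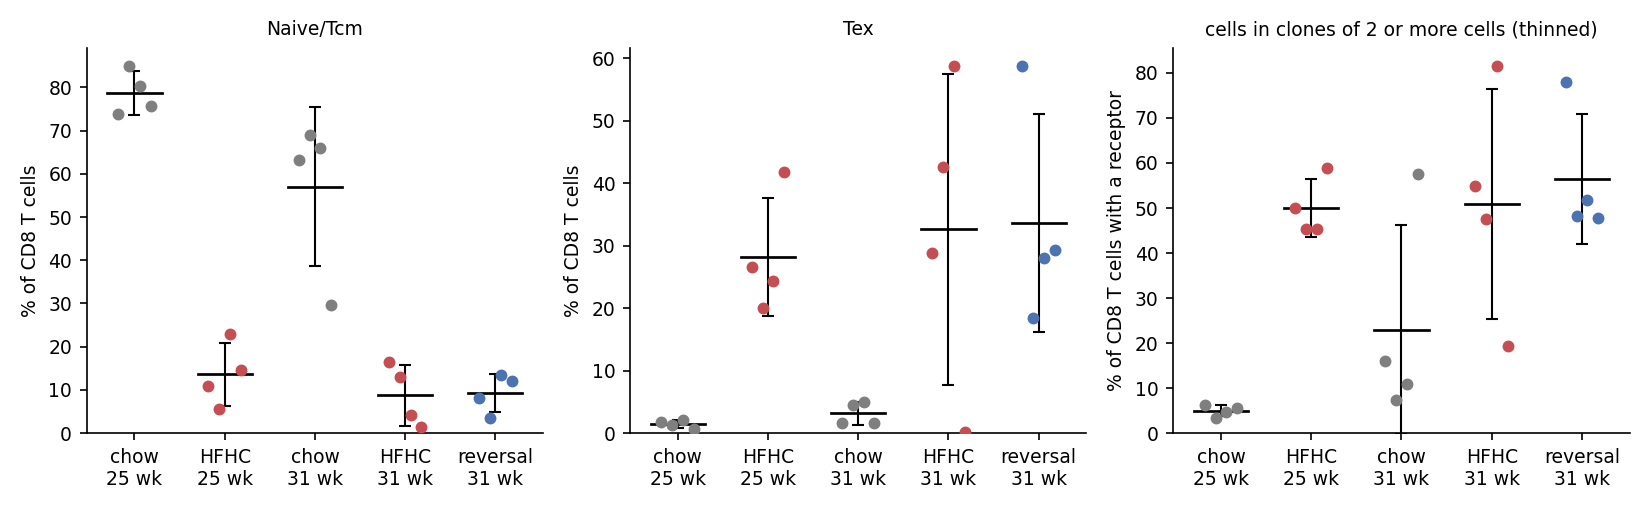
Naive/Tcm and Tex cells as a percentage of CD8 T cells, and cells of clones with 2 or more cells as a percentage of CD8 T cells with a receptor (vertical axes) in the 5 groups (horizontal axes), with 1 point per mouse, a black line at the mean and an error bar of 1 SD. At 25 weeks Tex cells averaged 28.2% on HFHC and 1.45% on chow, and cells of such clones 49.9% and 5.02%.

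Receptor sequences were used to ask whether CD8 T cells of the liver had expanded as clones. At 25 weeks, 49.9 ± 6.4% of CD8 T cells on HFHC belonged to clones of 2 or more cells and 5.02 ± 1.25% on chow, with each library thinned to 346 cells (2-sided exact permutation test, SD, n = 4 per group, p = 0.0286, BH over 4 comparisons 0.114). The probability that a pair of CD8 T cells shared a clone was 76.15-fold higher on HFHC (exact permutation p = 0.0286, BH 0.114). Naive/Tcm cells, more frequent on chow, were seldom in clones of 2 or more cells (1.41% over all libraries), so the mix of subsets enters both measures. Within Effector/Tem cells, not thinned, the shares at 25 weeks were 24.19 to 32.41% on chow and 38.64 to 64.3% on HFHC. At 31 weeks the expanded shares were 50.9 ± 25.5% on HFHC, 23.0 ± 23.3% on chow and 56.4 ± 14.4% after reversal, and no comparison passed (exact p = 0.171 for HFHC against chow, 0.886 for reversal against HFHC and 0.114 for reversal against chow). The probabilities differed 9.97-fold, 0.82-fold and 8.18-fold in these comparisons. As differences in log10 probability, that between HFHC and chow was 0.654 without HFHC library 3, 0.684 without chow library 2, 1.27 without HFHC library 4 and 1.504 without chow library 4. That between reversal and chow was 0.598 without chow library 2, 0.688 without reversal library 1, 1.11 without reversal library 2 and 1.419 without chow library 4 (exact permutation p = 0.0286, BH 0.0572). The difference between reversal and HFHC, 5.54 points, turned to −4.94 without HFHC library 4 and to −1.63 without reversal library 1. The difference in log10 probability, −0.086, turned to 0.258 without HFHC library 3 and to 0.113 without reversal library 2. Single clones weighed heavily at 31 weeks: the largest clone of HFHC library 3 had 1799 cells, 60.3% of its CD8 T cells with a receptor, and that of chow library 4 had 632 cells (31.4%), of which 99.8% were Effector/Tem cells.

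Expanded CD8 T cells were compared with cells of single-cell clones within each of the 20 mice. Cytotoxic genes were higher in expanded cells, with the granzyme genes Gzma at a log2 change of 2.79 (SE 0.30) and Gzmb at 2.63 (SE 0.22), and so were the inhibitory receptor genes Lag3 (2.61, SE 0.16), Tigit (2.04, SE 0.15) and Pdcd1 (2.41, SE 0.14), the last at 240 against 40.2 CPM and higher in 20 of 20 mice. Ccl4 (2.47), Ccl3 (2.40), Coch (2.14, higher in 18 of 20 mice), Adgrg1 (2.14), Gzmk (2.08), Cxcr6 (1.53), Tox (1.47) and Cd8a (0.81) were higher too. The naive cell gene Ccr7 (−4.14, SE 0.27) was lower in all 20 mice, together with Dapl1 (−3.87), Igfbp4 (−3.44), Actn1 (−2.82), Nsg2 (−2.81), Satb1 (−2.79), Tdrp (−2.71), Il6ra (−2.67) and Sh3bp5 (−2.56). In all, 4363 of 7892 genes passed, 3538 higher and 825 lower (limma, n = 20 mice). Of 16 exhaustion-associated genes 15 were higher, of 15 cytotoxic effector genes 13 were higher and 1 lower, and all 14 naive or central memory genes were lower, with the same counts adjusted over the list alone. Without clusters 1, 12 and 20, 4929 genes passed, 4039 higher and 890 lower (18 mice). Within Effector/Tem cells alone 329 genes passed, 160 higher and 169 lower. Cd8b1 (0.19, adjusted p 0.0759) and Cd4 (−0.17, adjusted p 0.635) did not pass by limma.

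The subsets that held expanded cells differed with diet. Of cells in clones of 2 or more, 53.2 ± 11.2% were Tex cells on HFHC and 12.5 ± 5.6% on chow at 25 weeks (2-sided exact permutation test, SD, n = 4 per group, p = 0.0286, BH over 3 subsets 0.0286), against 6.47 ± 2.61% and 0.68 ± 0.10% of single-cell clones. At 31 weeks the expanded cells were 53.0 ± 38.6% Tex on HFHC, 12.5 ± 11.6% on chow (exact p = 0.143) and 69.8 ± 15.1% after reversal (exact p = 0.0286 against chow, BH 0.0429, and 0.543 against HFHC). The HFHC value rests on library 4, whose CD8 T cells lay mostly in cluster 12 and whose expanded cells were 0.25% Tex. In HFHC libraries 1, 2 and 3 the shares were 49.35, 75.41 and 87.1%, against 2.01 to 27.19% on chow. These shares count cells, not clones. In HFHC library 3 the largest clone had 1799 cells, where 2612 were expanded, and 93.2% of it was Tex and 91.9% in cluster 11. By library, 25.0 to 98.14% of Tex cells, 24.19 to 87.36% of Effector/Tem cells and 0 to 8.33% of Naive/Tcm cells belonged to clones of 2 or more. The share was higher for Tex than for Effector/Tem cells except in chow libraries 1 and 4 and HFHC library 4 at 31 weeks, the last with 4 Tex cells.

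**Figure D4:**
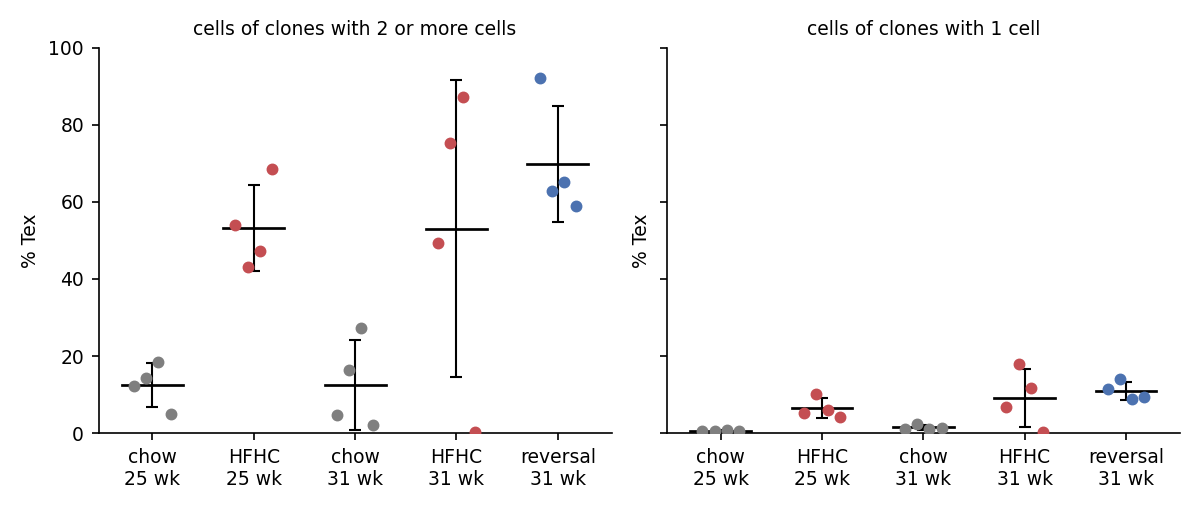
Tex cells as a percentage (vertical axis) of CD8 T cells in clones of 2 or more cells and of those in clones of 1 cell, in the 5 groups (horizontal axis), with 1 point per mouse, a black line at the mean and an error bar of 1 SD. At 25 weeks Tex cells averaged 53.2% of expanded cells on HFHC and 12.5% on chow.

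The use of V genes and the sharing of receptors asked whether diet selected the same receptors in different mice. No TRBV gene (20 tested) or TRAV gene (43 tested) passed in any of the 4 comparisons (2-sided exact permutation tests, n = 4 per group, each clone counted once), but with a smallest p of 0.0286 a single V gene cannot pass BH over 20 or 43 genes, so this does not show that diet selected none. At an unadjusted p under 0.05 there were 1 TRBV gene and 1 TRAV gene at 25 weeks, 1 and 3 for reversal against chow, and none in the other comparisons, and the lowest BH value was 0.410. With each cell counted, 4 TRBV genes and 6 TRAV genes had an unadjusted p under 0.05 at 25 weeks and 1 and 1 for HFHC against chow at 31 weeks. None did for reversal against HFHC, 0 and 2 did for reversal against chow, and none passed BH. Mice of the same diet shared 4.9 more TRB CDR3 amino acid sequences per 1000000 pairs of sequences than mice of different diets at 25 weeks (exact permutation p = 0.0857) and 1.51 more at 31 weeks (exact permutation p = 0.343). The 25-week value includes receptors shared by HFHC libraries 21, 24 and 25, of which 19 were identical in nucleotides. With both chains the values were 3.46 (exact permutation p = 0.143) and −0.16 (exact permutation p = 1.0). With only expanded clones the 25-week value was −91.53 (exact permutation p = 0.371), and at 31 weeks only 1 of 28 pairs of mice shared any sequence.

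In CD4 T cells the diet effect was measured on a class whose clusters did not all carry CD4 T cell markers: its cluster 0 was led by Il4 and Zbtb16, as natural killer T cells are, and its cluster 15 by the gamma-delta T cell genes Cd163l1 and Trdv4. At 25 weeks Nrp1 (log2 change 1.96, adjusted p 0.0387), Ctla2a (2.20, adjusted p 0.0346), Ahr, a sensor of environmental ligands (1.65, adjusted p 0.000734), and Il1rl1, the interleukin 33 receptor (1.82, adjusted p 0.0400), were higher on HFHC by limma, and Cd7 was lower (−1.85, adjusted p 0.00617). At 31 weeks the 8 genes that passed included Krt83 (2.09), Ahr (1.38), Nt5e (1.38), Epas1 (1.27), Dennd4c (1.01) and Ifngr1 (0.89), higher, and the Notch regulator gene Dtx1 (−1.22), lower. These CD4 genes were picked out after their values were seen. The class itself shifted, with a Naive/Tcm share of 39.12 to 67.37% on chow and 4.366 to 37.26% on HFHC at 25 weeks. Within cluster 0 alone Ctla2a (1.23), Ahr (1.65) and Cd7 (−4.44) passed at 25 weeks. Nrp1 and Il1rl1 were too low to be tested there and in the Naive/Tcm cluster. Within the latter Ctla2a passed (2.28) and Cd7 had a log2 change of 0.38 (adjusted p 0.920, limma). None of the genes named for 31 weeks passed within cluster 0 (Ahr 0.99, adjusted p 0.336, limma). Nor did those tested within the Naive/Tcm cluster, where Krt83, Ahr and Epas1 were too low to be tested. Within cluster 0 all the genes named for 31 weeks kept their direction, with Dtx1 at −1.87 (adjusted p 0.0658) and Nt5e at 1.17 (adjusted p 0.115) by limma. Within the Naive/Tcm cluster Dtx1 turned to 0.47 (adjusted p 0.866) and Nt5e to −0.02 (adjusted p 0.995). A change in the mix of cell types is therefore not excluded for these. Of 8244 genes 119 passed at 25 weeks (90 higher, 29 lower) and 8 at 31 weeks (7 higher, 1 lower). For reversal against HFHC 329 passed (281 higher, 48 lower), and for reversal against chow 1220 (1042 higher, 178 lower), with a median change of 0.113 log2 in the last (limma). Within cluster 0 alone the 4 counts were 649, 3, 1 and 7. Within the Naive/Tcm cluster alone they were 6, 0, 23 and 0 (limma, 422 and 599 genes at an unadjusted p under 0.05 for the counts of 0), and without cluster 13, 209, 2, 1 and 10. For 25 weeks the count was 49, 47 and 70 without chow libraries 16and19, 17 and 20, and 49 and 75 without HFHC libraries 23 and 24. For 31 weeks it was 5, 2 and 4 without chow libraries 1, 2 and 4, and 3 and 5 without HFHC libraries 2 and 3. For reversal against HFHC it was 62, 136, 1313 and 42 without HFHC libraries 1 to 4 in turn, and 57 and 4 without reversal libraries 1 and 2. For reversal against chow it was 604 and 780 without chow libraries 2 and 4, and 525 without reversal library 2.

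Within each CD8 subset fewer genes passed than over all CD8 T cells, in each comparison given here. Among Effector/Tem cells 0 genes passed for HFHC against chow at 25 weeks, for HFHC against chow at 31 weeks and for reversal against HFHC (limma, 682, 666 and 1927 at an unadjusted p under 0.05), and 3188 passed for reversal against chow, 2023 higher and 1165 lower. This subset included clusters 1, 12 and 20. Among CD8 Naive/Tcm cells 5, 0, 14 and 8 genes passed in the same order (limma, 485 at an unadjusted p under 0.05 for the count of 0). Among regulatory T cells 386 passed at 25 weeks, 289 higher and 97 lower, and 0 in the other comparisons (limma, 320, 142 and 239 at an unadjusted p under 0.05). Tex cells were not compared at 25 weeks, where only 1 chow library had enough of them. At 31 weeks 9 Tex genes passed for HFHC against chow and 17 for reversal against chow, and 0 for reversal against HFHC (limma, 92 at an unadjusted p under 0.05). Only 3 HFHC libraries had enough Tex cells there, without library 4. Chow libraries 1 and 4 had 35 and 36 Tex cells with a receptor. The small counts therefore do not show that Tex cells differed little.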

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

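Of the tests in this part, that of whether cells without Cd8 transcripts lowered Pdcd1 in HFHC library 4 was planned before its result was seen, and the others were chosen after the results they bear on had been seen.

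HFHC library 4 at 31 weeks stood apart from the other 3 libraries of its group: pancreatic enzyme genes averaged 3491.5 CPM over all its cells, against at most 80.3 CPM in any other library, and its Effector/Tem share of all cells was 89.87% (37.5% in the next library). The pancreatic level in its cells with a Cd4 UMI was 1.085 times that in its cells with a Cd8 UMI, which is consistent with free pancreatic RNA in the droplets, and a pancreatic UMI in 99.9% of cells argues against T cells captured together with pancreatic cells, an explanation tested first and then replaced. An exchange of labels with chow library 4 is argued against: along the HFHC effect of the 25-week mice over 3951 genes that library stood at 0.21 (chow libraries 1 to 3 at −0.08 to 0.057, HFHC libraries 1 to 3 at 0.638 to 0.922, and HFHC library 4 itself at 0.128, nearer to chow), with Pdcd1 at 15.77 CPM and Tex cells at 1.58%, although its Naive/Tcm share of 29.61% (63.15 to 69.07% in the other chow libraries) and Cxcr6 at 307.4 CPM (73.96 to 125.1) were nearer to HFHC and the exchanged split called 2392 genes against 1135. The annotation alone is argued against, since the library's CD8 cells chosen by transcripts had Pdcd1 at 18.2 CPM, against 117.5, 217.4 and 277.4 CPM in the other 3. A single wrong label and a mouse that responded less to the diet stay open and were not tested.

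The count of 989 genes between reversal and HFHC in CD8 T cells rested on cells of cluster 1: without that cluster alone 5 genes passed, and the 931 called genes still measured kept a median of 25.5% of their log2 change (quartiles 10.5 and 41.55%), which is consistent with a larger share of shallow cells in the reversal libraries. Of the called genes 98.7% had the sign of the difference between cluster 1 and other CD8 T cells, but so did 82.9%, 86.9% and 95.4% for HFHC against chow at 25 and 31 weeks and reversal against chow. The 5 dissociation stress genes called kept a median of 93.52% without cluster 1, but none passed, and they had been called with that cluster included. Hspa1a kept 101.8%, Hspa1b 99.28%, Dnajb1 93.52%, Hspa8 62.98% and Hsp90ab1 56.76%. Most of the change of Hspa1a, Hspa1b and Dnajb1 thus stayed without the shallow cells, and for Hspa8 and Hsp90ab1 their part cannot be told. The count also depended on HFHC library 4, since without it 59 genes passed. The 989 genes then kept a median of 77.87%, all in the same direction. They had been called with that library included, which favours such a result, so whether that library alone gave the count cannot be told. An effect of the change of diet within the other CD8 T cells cannot be told apart from none, because without clusters 1, 12 and 20 the called genes kept a median of 28.01% with an upper quartile of 52.35%, and 3 genes passed. Whether the shallow cells reflect the diet or the handling of the libraries stays open and was not tested.

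HFHC libraries 21, 24 and 25 at 25 weeks shared 19 receptors with identical nucleotide sequences in both chains, 8.33 per pair of libraries against 0.144 for other pairs. Among these, 57.9% had 10 or more cells in the library that held most, against 1.35% of all 3565 receptors of these libraries (Fisher's exact test, 2-sided, p = 5.42e-17), which is consistent with material of large clones carried from 1 library into another. Reads assigned to the wrong library with their barcode are argued against by 0 shared barcodes. The same receptor formed independently in each mouse is argued against, since elsewhere 90.1% of matches in amino acids were not matches in nucleotides. The other copies held 29 cells in all, and a biological explanation was not tested.

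The gap between a single library and the next made up most of the range of its group in 31 of 365 tests (8.49%), where chance gives about 1 in 20 groups. This marks a relative gap, and the difference itself could be small. Polr2j in chow library 3 at 31 weeks compares with 63.32 to 63.49 CPM in the other 3. Dnajb1 in chow library 20 at 25 weeks compares with 479.1 to 483.2 CPM. Chow library 4 at 31 weeks had 7 of them: Naive/Tcm cells at 29.61% of CD8 T cells, and in CD8 T cells Ccr7 at 201.0, Fam241a at 102.3, Ier5l at 14.81, Nsg2 at 41.03, Tdrp at 26.09 and Ubb at 4259 CPM. In chow library 3 at 31 weeks Adgrg1 was at 4.979, Pdcd1 at 27.65 and Polr2j at 65.83 CPM, and in chow library 2 Penk was at 5.98 CPM. In HFHC library 4 at 31 weeks Cd8b1 was at 530.7 CPM. Reversal library 1 had 77.91% of its CD8 T cells in expanded clones and Sh3bp5 at 11.4 CPM. In reversal library 2 Malt1 was at 710.1, Polr2j at 24.61 and Rgcc at 85.78 CPM. At 25 weeks, chow library 17 had CD4 Naive/Tcm cells at 19.66% of all cells, Fcgrt at 43.92 CPM and Penk at 4.277 CPM. Chow library 20 had Treg cells at 5.63%, Dnajb1 at 525.9 CPM and Nrp1 at 42.06 CPM, and in chow library 16and19 Ern1 was at 13.48 CPM. HFHC library 23 had NK/NKT cells at 1.32% of all cells, Ccr9 at 0.0 CPM and Slc25a36 at 32.6 CPM. HFHC library 24 had Treg cells at 11.89%, HFHC library 21 Ctla4 at 387.0 CPM, and HFHC library 25 Fosl2 at 21.21 CPM.

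The diet effect in CD8 T cells differed between 31 and 25 weeks, by the test of the difference itself (limma), for Ifi208 (1.298 log2), Ankrd37 (−1.473), Bex3 (−0.7091), Icam1 (−0.8549) and Fkbp5 (−1.192). Duration and a batch of animals cannot be told apart in this test, because the times were measured in different mice. Another split of the mice gave 82 genes in it, so chance was not taken as excluded. The difference between expanded and single-cell clones itself differed with diet for 313 genes at 25 weeks (42 higher and 271 lower on HFHC), 3 at 31 weeks (0 and 3) and 194 between reversal and chow (5 and 189 after reversal, limma). The single-cell clones it is taken against were unlike cells in these groups. The expanded cells differed in their mix of subsets too, at 25 weeks and between reversal and chow. A signal outside the comparisons was cluster 20, led by Fabp1, with 493 of its 494 cells from HFHC library 21 at 25 weeks.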

How the results depend on the processing

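The tests with only the 31-week mice in the model, without whole clusters, with only cells with a receptor, only cluster 0 or only the CD4 Naive/Tcm cluster, with median-centred values in the sets followed from 25 weeks and over other splits of the mice were chosen after the results were seen. Where a value moved, the cause was not tested, except that a filter at 50 CPM and the single clusters test fewer genes or cells.

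Among main results, 172 values under other settings kept their direction and side of the threshold or moved little, 87 moved, 7 reversed, 3 became weaker and 1 stronger. Among single genes and gene lists 1482 values stayed, 386 became weaker, 41 stronger and 8 reversed. Counts below are of genes called, in the order HFHC against chow at 25 weeks, HFHC against chow at 31 weeks, reversal against HFHC, reversal against chow and the difference between 31 and 25 weeks, as far as they moved by more than 1.5 times.

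For CD8 T cells (3951, 1135, 989, 4584 and 5), a filter at 50 CPM gave 1893 at 25 weeks, 2142 for reversal against chow and 3 for the difference. No filter gave 341 and 122 in the middle pair of comparisons. The mean of log values gave 755, 73 and, for the difference, 78. Only the compared groups in the model gave 3 and 0, only the 31-week mice 94 and 3, and a block on the replicate number 3 and 1. The numbers did not pair the mice: 2 of 12 libraries correlated best with a library of their own number, and the median correlation of equal numbers was −0.037 against 0.026. Recovered UMIs gave 12 for reversal against HFHC and 11 for the difference, and CD8 cells by transcripts 10 and 13. A median gene set equal gave 2397 at 25 weeks and 1 for the difference, as did a pseudocount of 1 CPM for the latter. A fixed mix of subsets gave 2, 0, 9, 2696 and 0. Without clusters 1, 12 and 20 the counts were 2410, 698, 3, 1264 and 1, and with the median gene set equal as well 2187, 608, 4, 1039 and 0. Without cluster 1 they were 5 for reversal against HFHC, 1803 for reversal against chow and 21 for the difference. Without cluster 12 they were 454 for reversal against HFHC and 2 for the difference, and with only cells with a receptor 8, 2276 and 27 for the last 3.

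For CD4 T cells (119, 8, 329 and 1220), no filter gave 40, 0, 92 and 762, a filter at 50 CPM 60 and 4 in the first pair, and a pseudocount of 20 CPM gave 5 at 31 weeks. The mean of log values gave 205, 3, 13 and 359, and only the compared groups 63, 13, 12 and 1948. The block gave 26 at 31 weeks, and only the 31-week mice 18 there and 108 for reversal against HFHC. Recovered UMIs gave 11 and 109 for the reversal comparisons, and a median gene set equal gave 152 for reversal against HFHC. Without cluster 13 the counts were 209, 2, 1 and 10, with only the Naive/Tcm cluster 6, 0, 23 and 0, and with only cluster 0 649, 3, 1 and 7. The expanded-clone count (4363) was 329 within Effector/Tem cells and 2205 at 50 CPM.

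Of gene lists called by camera (5, 5, 3 and 4), 0 were called with an estimated correlation in each comparison, and fry called 15, 10 and 15 in the 2 HFHC comparisons and in reversal against chow. The cholesterol synthesis list at 25 weeks had the opposite direction by fry (adjusted p 0.01461). In genes higher at 25 weeks, the median change of 0.2187 in reversal against HFHC lost its fry call with the block (0.2187), without clusters 1, 12 and 20 (0.0788) and with the median gene set equal (0.133). In genes lower at 25 weeks it gained the call with the median gene set equal (−0.2391). With a fixed mix of subsets Cxcr6 (−0.152) and Gzmb (−0.192) at 25 weeks, Cxcr6 (−0.108) and Gzmk (−0.146) at 31 weeks, and Cxcr6 (−0.217) and Gzmk (−0.119) in reversal against chow reversed, as did Gzmb at 31 weeks (−0.5674) and in reversal against chow (−0.4894), not past the threshold in either setting. Without cluster 1, Slc25a36 reversed for reversal against HFHC (−0.009406). For reversal against HFHC the expanded share reversed with clones of 5 or more (−0.344) and 10 or more cells (−3.861), and the log10 clone probability without the largest clones (0.053) and without clusters 1, 12 and 20 (0.083). Shared CDR3 sequences reversed with both chains at 31 weeks (−0.16) and with only expanded clones at 25 weeks (−91.53), while at 31 weeks the latter (−34.72) rests on 1 of 28 pairs of mice, too few for a direction. With permutation within replicate numbers 0 of 3 CD8 subsets passed for reversal against chow, in place of 2, since 16 arrangements are too few for a p under 0.05.

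Leaving out each library in turn gave 3147 to 3749, 140 to 3078, 59 to 2247, 3892 to 4572 and 2 to 8 genes in CD8 T cells, 47 to 131, 2 to 9, 4 to 1313 and 525 to 1372 in CD4 T cells, and 4077 to 4769 for expanded clones. The ranges were 13.6 to 17.1, 27.9 to 38.0, −18.0 to −8.88 and 14.1 to 25.3 points for the CD8 share, 41.9 to 46.4, 17.7 to 39.4, −4.94 to 15.8 and 26.2 to 44.9 points for the expanded share, and 1.72 to 2.08, 0.654 to 1.5, −0.36 to 0.258 and 0.598 to 1.42 for the log10 probability. They were 0.1084 to 0.2915 and −0.249 to −0.0891 for the medians of genes higher and lower at 25 weeks. Of single genes 722 stayed, 114 became weaker and 4 stronger.

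Chance was taken as excluded where the share of splits of the same mice with as many genes was under 0.05. For CD8 T cells at 25 weeks 1 of 35 splits did, the real one (highest other 0), for reversal against chow 1 of 35 (423) and for expanded clones 1 of 100 (1). For the difference between 31 and 25 weeks 2 of 100 did, but another split gave 82 genes against 5. Chance was therefore not taken as excluded there. For CD4 T cells 1 of 35 did at 25 weeks (19), at 31 weeks (0) and for reversal against chow (1). Chance could not be excluded for CD8 T cells at 31 weeks, where 4 of 35 splits gave 1135 genes or more and chow libraries 1, 2 and 3 with HFHC library 4 against the other 4 gave 2392, for reversal against HFHC (3 of 35, highest other 1489), or for the latter in CD4 T cells (3 of 35, 940 against 329). Why such splits gave more genes was not tested.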

Other observations

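The tests of the difference between expanded and single-cell clones by diet and of Tex cells in expanded clones were chosen after the results were seen.

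Members of other lists also passed singly in CD8 T cells at 25 weeks, when 3951 of all 8133 genes did. Of 16 chemokine and cytokine receptor genes 8 rose, of 14 tissue residency genes 7 rose and 1 fell, of 11 T cell receptor signalling genes 7 rose and 1 fell, of 11 AP-1 and NF-kB regulators 7 rose, of 11 fatty acid genes 6 rose and of 11 proliferation genes 6 rose, each over all genes and adjusted over the list alone. Of 13 glycolysis genes 7 rose and 8 adjusted over the list alone. Of 14 cholesterol synthesis and uptake genes 4 rose and 1 fell (4 and 0 adjusted over the list alone), of 16 interferon response genes 4 rose and 1 fell (2 and 1), of 19 dissociation stress genes 3 rose and 1 fell (2 and 1), and of 10 circulating effector genes 2 rose, of 5 cholesterol efflux genes 2, of 6 CD4 markers 3 and of 4 Th1 or follicular helper markers 2, with the same counts adjusted over the list alone. Of 5 CD8 markers 2 rose and 1 fell by either adjustment. By camera these 15 lists did not pass, with adjusted p from 0.0932 to 0.893. With the median gene set equal, 3 cholesterol synthesis and uptake genes fell and none rose at 25 weeks, and no glycolysis gene passed.

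Markers of other cells were mostly below the expression filter in CD8 T cells. No gene of the macrophage or Kupffer, dendritic, stellate, red cell or platelet and Th17 lists reached it. At 25 weeks Igkc, an immunoglobulin light chain gene, was higher on HFHC by 2.27 log2 and Ighm lower (−1.65), and Xbp1 of the plasma cell list (0.64), Epcam of the cholangiocyte list (1.35), Tcrg-C2 of the gamma-delta list (1.47), Slamf1 of the natural killer T list (1.52) and Rora (1.26) and Gata3 (0.41) of the Th2 list were higher (limma). Pecam1 of the endothelial list was lower (−1.03). Fabp1 of hepatocytes (1.90, adjusted p 0.179), Klrb1f of natural killer cells (−0.50, adjusted p 0.457), Mmp9 of neutrophils (−0.74, adjusted p 0.403) and Tcrg-C4 (0.68, adjusted p 0.0541) did not pass by limma. T cells themselves express Xbp1, Pecam1, Slamf1, Rora and Gata3.

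The difference between expanded and single-cell clones itself differed with diet at 25 weeks for genes picked after their values were seen. The single-cell clones it is taken against were unlike cells, 86.46% Naive/Tcm and 12.87% Effector/Tem on chow and 41.9% and 51.63% on HFHC. The expanded cells were unlike too, 70.6% Effector/Tem and 12.48% Tex on chow and 46.31% and 53.17% on HFHC. They numbered 20 to 90 per chow library and 179 to 2728 per HFHC library. An effect of diet on expansion cannot be told apart from these mixes. The log2 difference between expanded and single-cell clones was smaller on HFHC than on chow for Cx3cr1, a receptor of circulating effector cells (−2.73, adjusted p 0.00631), Klrg1, a marker of short-lived effector cells (−1.97, adjusted p 0.0203), and Gzmk (−1.96, adjusted p 0.00777), and larger for Coch (3.39, adjusted p 0.0117), by limma. Of 4 clones above 500 cells, with 3980 cells, the authors' size class was empty.

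Expanded clones in HFHC livers held more Tex cells than those in chow livers, and whether by more than the general shift of CD8 T cells towards Tex would give cannot be told apart, because the answer depends on the scale. At 25 weeks the Tex share of expanded minus that of single-cell clones was 46.7 ± 13.4 points on HFHC and 11.8 ± 5.5 on chow (SD, n = 4 per group), a difference of 34.9 points (2-sided exact permutation test, p = 0.0286). In log odds of Tex the same differences were 2.85 ± 0.84 and 2.95 ± 0.45, a difference of −0.1 (exact p = 0.886). Tex cells were named on the same cells.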
